A study of Mus musculus with 2 samples.

How the data were processed

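Total RNA from 2 primary cultures of mouse RPE was amplified, labelled with biotin and hybridised to arrays, 1 per culture, per the labels' protocols. The cultures were grouped by their titles into untreated RPE and RPE with IFNg. The deposited values are probe-set signal intensity on a linear scale, from 0.1 to 14896 over 45101 probe sets, on an Affymetrix mouse expression design. The mean of each deposited array after trimming 2% at each end was 100, as seen in the values. The summarisation software, the background correction and the detection calls are not given in the sources used here, so a floor on dim signals took the place of detection calls. The labels describe serum-free culture overnight before RNA extraction for both cultures and do not say how it overlapped with the 24 h of IFNg.

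Before the data were examined, the comparisons of the report, 25 gene lists, the rule for named genes and the processing alternatives were fixed. The 64 control probe sets were left out, which left 45037. Each array was scaled to a common 2% trimmed mean (factors 0.999924 and 1.00008, which leaves the deposited values practically as they were). Signals under the pooled median, 20.4, were set to it, and log2 was taken. At this floor, 49.7% of untreated and 50.4% of IFNg probe sets counted as measured. How much background a signal near the floor holds is not known, so ratios of dim genes are uncertain in size. A ratio with 1 array at the floor is a bound.

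Gene names came from the platform's probe annotation, which can be old and in which 34945 probe sets have 1 gene, 932 have several and 9160 have none. Genes were named only from probe sets with 1 gene. Of the annotation's rows, 96.8% had an Entrez identifier found in the reference gene table of assembly GRCm38.p6, and 0 symbols changed. No coordinates are given, since no genome build is named for the deposited signals. A gene took its value from the probe set with the highest mean log2 signal among those naming it alone, which gave 18193 genes, 12753 of them above the floor on 1 or both arrays and 5440 at the floor on both. Of 624 list symbols, 555 matched directly, 5 through a synonym and 64 not at all.

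With 1 array per group there was no test. Genes were counted at 2-fold when the brighter array was above the floor. The rule for named genes took Cd274, the 12 highest and 12 lowest log2 ratios among genes above the floor on both arrays, the 8 highest bounds in each direction among genes with 1 array at the floor, and within each list up to 4 members with the largest difference and any member 2-fold the other way. Further list members were named to show values within 2-fold. Genes named in the closing section by family were chosen after their values were seen. Each list's median log2 ratio, over members above the floor on 1 or both arrays, was placed among medians of 10000 random gene lists of equal size drawn from 20 bins of mean log2 signal. Medians include members at their bound.

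The lists were IFNg receptor, JAK-STAT and IRF signalling; class I presentation and immunoproteasome; class II presentation; T-cell ligands and adhesion molecules; guanylate-binding proteins and immunity-related GTPases; chemokines and cytokines; type I interferon-stimulated genes. They also covered immunosuppressive factors of ocular pigment epithelium, complement, RPE markers and visual cycle, melanogenesis, epithelial junctions, fibroblast and mesenchymal genes, and markers of macrophages, of T, B and NK cells, of endothelial cells and pericytes, of photoreceptors and neural retina, of lens and ciliary or corneal epithelium and of Schwann cells and the melanocyte lineage. The last 6 were proliferation, apoptosis and inflammatory caspases, cholesterol synthesis, immediate-early and stress response, tryptophan, arginine, nitric oxide and redox metabolism, and housekeeping genes. Some genes stand in more than 1 list, for example Ciita, Nos2, Cybb, Ctsl and Rlbp1.

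The alternatives were the deposited values without rescaling, a common 75th percentile, quantile normalization, a loess curve of the log2 ratio on mean signal, floors at the pooled 25th and 75th percentiles, a pseudocount of 16 in place of the floor, averaging of all probe sets per gene, leaving out probe sets whose IDs mark shared sequence, thresholds of 1.5-fold and 3-fold, and random lists without matching. Analyses used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.

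The procedure was tested on simulated arrays made from the real signals of 12100 genes with noise at the SD of 0.44 seen between probe sets of a gene. Of 50 genes set 4-fold higher, 98% passed 2-fold, and of 50 set 4-fold lower, 84% did. Of genes set at exactly 2-fold, 50% passed in each direction, as noise falls evenly about the threshold. Of 11900 genes with no difference, 2.03% passed 2-fold, and a list of 20 genes set 2-fold higher reached percentile 100. This noise is technical and leaves out differences between cultures. It had the same SD at every brightness, taken from probe sets above the floor on both arrays. In the data, genes past 2-fold were more frequent among dim genes. In bin 3 of 10 from the dimmest, 199 of 1275 were higher and 175 lower, against 57 and 13 of 1276 in the brightest. The 2.03% therefore does not estimate how many calls in the data are noise.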

Results

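Transcripts were measured in primary cultures of mouse retinal pigment epithelium (RPE), the pigmented cell layer that lies behind the photoreceptors. There were 2 cultures, each hybridised to 1 oligonucleotide array. The first was left untreated, and the second received interferon gamma (IFNg), a cytokine made by T cells and NK cells, at 100 U/ml for 24 h. Both had been grown for 14 days and were described as mostly cytokeratin-positive. Each array gave a signal for 45101 probe sets, with a median of 20.1 on the untreated array and 20.8 on the array of the IFNg-treated culture (the IFNg array). Neither group had a replicate, so no p-value exists for any difference, and the number of arrays limits the precision. The words higher and lower therefore describe these 2 arrays. Signals were floored at 20.4, the pooled median, and where 1 array lay at this floor the fold against it is a lower bound, given as "at least".

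The series concerns PD-L1, a ligand of the inhibitory T-cell receptor PD-1, on RPE cells exposed to IFNg. Cd274, the gene for PD-L1, was at least 20.6-fold higher with IFNg. Its single probe set had a deposited signal of 13.6 on the untreated array, which lies under the floor, and 419.5 on the IFNg array. With a floor at the pooled 75th percentile the bound was 4.84-fold. Pdcd1lg2, the gene for the second PD-1 ligand PD-L2, was at the floor on both arrays, with signals of 2.1 and 4.6.

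Among 17 measured genes for T-cell costimulatory and coinhibitory ligands and adhesion molecules, 5 were at least 2-fold higher with IFNg, none was 2-fold lower and 12 lay between. The 5 were Cd274, the leukocyte adhesion molecules Vcam1 (2.93-fold) and Icam1 (2.23-fold), the death ligand Tnfsf10 (at least 2.87-fold) and the costimulatory ligand Cd80 (2.28-fold). Cd47, a ligand that inhibits phagocytosis, was 1.91-fold higher (log2 ratio 0.93), with 1.27 and 1.13 for further bright probe sets and -0.77 for a dim one. Cd276, another B7-family ligand, had signals of 174 and 164 and lay within 2-fold. The list's median log2 ratio was 0.50, at percentile 99.7 among 10000 random gene lists of the same size matched on mean expression. Here and for the lists that follow, such a percentile is a description of these 2 arrays and not a test. A further 9 members, among them the costimulatory genes Cd86 and Tnfsf4, were at the floor on both arrays.

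**Figure D1:**
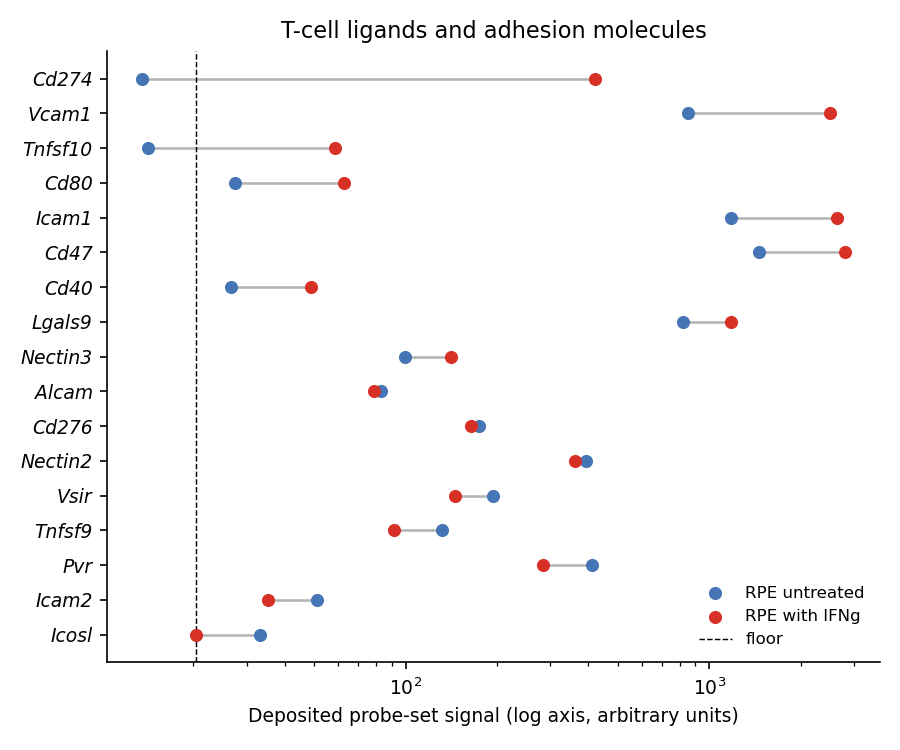
Deposited probe-set signal of 17 genes for T-cell ligands and adhesion molecules on the untreated array (blue) and the IFNg array (red), on a log axis in arbitrary units, with the floor as a dashed line. Cd274 goes from 13.6, left of the floor, to 419.5, and each point is a single array without an error estimate.

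Across the transcriptome, the genes with the greatest excess on the IFNg array included genes for chemokines, guanylate-binding proteins, immunity-related GTPases and antigen-presentation proteins. Cxcl9, a chemokine that attracts activated T cells, had the highest fold of all genes measured on both arrays, with signals of 32 and 9127 (285-fold). It was followed by the GTPase genes Gbp6 (131-fold) and Gm4951 (74.5-fold), the class II invariant chain Cd74 (68.3-fold), the GTPase Iigp1 (67.1-fold), Ifit2 (43.2-fold), Gbp2 (42.8-fold), Gbp7 (42.4-fold), the chemokine Cxcl10 (37.8-fold), Igtp (37.3-fold), the immunoproteasome subunit Psmb9 (36.6-fold), the transcription factor Irf8 (30.4-fold) and Rsad2 (28.4-fold). With a floor at the pooled 75th percentile the folds of 6 of these 13 genes, with untreated signals of 32 to 41, became bounds over 1.5 times smaller: Cxcl9 at least 105-fold, Gbp6 62.2-fold, Gm4951 27.5-fold, Cd74 26.8-fold, Ifit2 17.8-fold and Irf8 11.4-fold. Gm4951, a gene-model symbol that the naming rule skips, is named here as a member of the GTPase list. Of genes at the floor on the untreated array, the highest bounds belonged to Calhm6 (at least 97.2-fold), the class II chain H2-Aa (at least 76.0-fold), the perforin-like Mpeg1 (at least 43.5-fold), Gbp8 (at least 39.6-fold), H2-Eb1 (at least 37.1-fold), the ubiquitin-like modifier Ubd (at least 32.6-fold), the class I transactivator Nlrc5 (at least 22.4-fold) and Acod1, which makes itaconate (at least 22.3-fold). A clone-named gene model among these was skipped, as was a RIKEN clone among the lowest genes above the floor on both arrays.

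Genes lower on the IFNg array differed by smaller factors. With both arrays above the floor, the histone gene H2bc22 was 7.86-fold lower, Vat1l 7.05-fold, Fam107a 6.15-fold, the lipid-droplet gene Plin4 5.21-fold, Gxylt2 5.09-fold, Cobl 4.76-fold, Sipa1l3 4.24-fold, Kazald1 4.18-fold, Ctu1 4.07-fold, Fbxo44 4.06-fold, Entpd6 4.04-fold and the ribosomal protein gene Rpl39 3.68-fold. Of genes at the floor with IFNg, Kptn was at least 6.80-fold lower, Plk3 at least 4.38-fold, Prrt4 at least 4.24-fold, Ighm at least 3.69-fold, the cation channel Trpv4 at least 3.49-fold, Sbk1 at least 3.45-fold, Tspan10 at least 3.43-fold and the bicarbonate transporter Slc4a5 at least 3.42-fold. Other measured probe sets of Kptn (log2 ratio at least 0.64), Prrt4 (at least 0.29) and Ighm (at least 0.06), dim and under the floor on the untreated array, went the other way. Further ones of Prrt4 (-0.65), Ighm (-0.22) and Fam107a (-0.47) were dim and under the floor with IFNg, so these bounds on a decrease show no disagreement. Another Fam107a probe set, also under the floor with IFNg, was at -2.73. The lower genes named with both arrays above the floor had dim IFNg signals, from 26.3 (H2bc22) to 62.9 (Plin4). With a floor at the pooled 75th percentile, which lies above these signals, their folds become smaller bounds. The genes named at the floor with IFNg had untreated signals from 69.7 (Slc4a5) to 138.8 (Kptn), so that floor lowers their bounds too. H2bc22 has 1 probe set, whose ID marks shared or cross-hybridising sequence.

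By number, 1124 genes were at least 2-fold higher with IFNg and 571 at least 2-fold lower, of 12753 genes above the floor on 1 or both arrays. At 4-fold the numbers were 159 and 15, and at 8-fold 60 and 0. Large decreases of dim genes are capped by the floor, so the 2 directions are not on equal terms. The untreated array was at the floor for 150 of the 1124 genes, and the IFNg array for 126 of the 571. Log2 signals of the 10447 genes above the floor on both arrays correlated with r = 0.912 across genes, which are not independent replicates. The only spread the design gives is technical: probe sets of the same gene differed in log2 ratio with an SD of 0.44 (4422 genes). Of the other probe sets of the higher genes, 87.5% of 1330 were also higher and 38.0% also passed 2-fold, against 74.4% and 22.3% of 301 for the lower genes. A second probe set was over 1 log2 unit away, still higher, for Cxcl9 (log2 ratio 6.82), Gbp6 (5.98), Rsad2 (3.75) and Erap1 (2.36), and lay within 2-fold for Idi1 (0.37), Hspa5 (-0.06, with a brighter one at 0.62) and Csf1r (-0.28). For H2-Aa (at least 4.52), Psmb8 (at least 2.19), Parp14 (at least 1.97), Tap1 (at least 0.80) and Cxcl11 (at least 0.54) it was under the floor on the untreated array, so these bounds show no disagreement. For Hsp90aa1 (-0.27), Ttr (-0.55) and Tyrp1 (0.33) such a probe set was dim and under the floor on 1 array, and further ones passed 2-fold in the direction of the chosen one (1.35 and 1.47, -1.19 and -1.45). Conversely, Adar (at least 1.98) and Acta2 (-1.41), within 2-fold by their brightest probe set, each had a dimmer one past it. The counts depend on the floor and the probe-set rule, at 2258 higher and 2059 lower with a floor at the pooled 25th percentile, 574 and 163 at the 75th percentile, and 591 and 357 with probe sets averaged per gene.

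**Figure D2:**
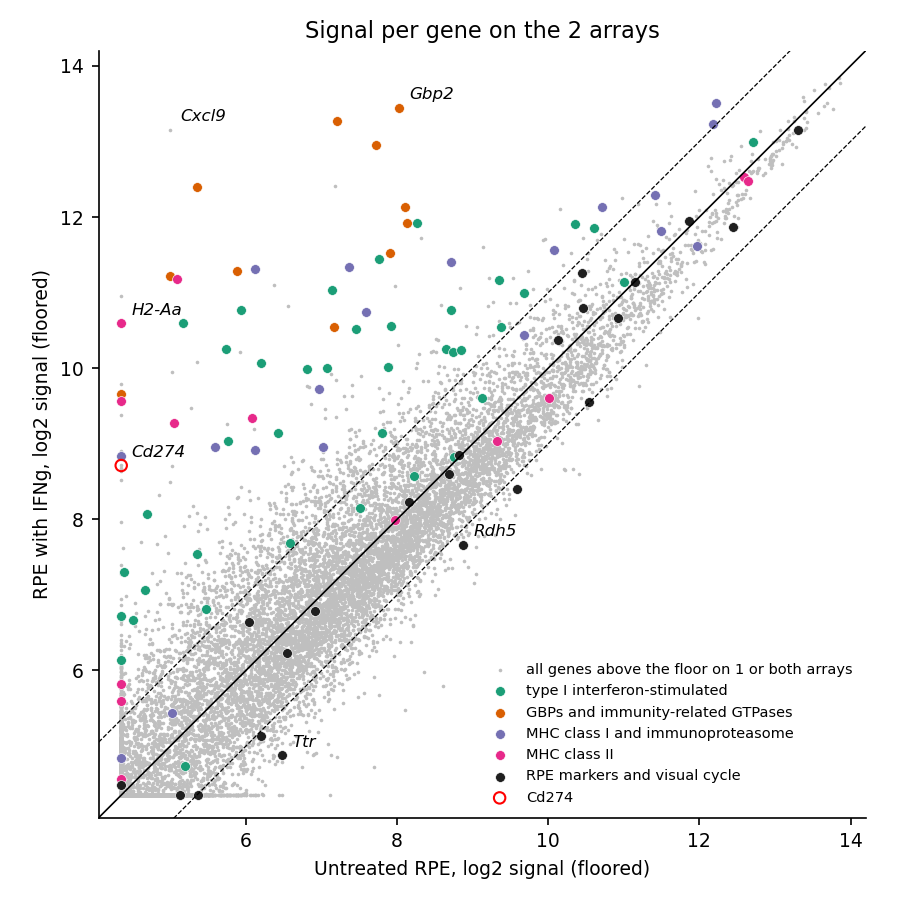
Floored log2 signal of each gene above the floor on 1 or both arrays, untreated RPE on the x axis and RPE with IFNg on the y axis, with the line of equality and dashed lines at 2-fold. Members of 5 gene lists are coloured, 1124 genes lie on or above the upper dashed line and 571 on or under the lower one, and genes at the left or lower edge are at the floor.

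Guanylate-binding proteins and immunity-related GTPases, which act against intracellular pathogens, were higher with IFNg in all 11 measured members, by 10.4-fold (Gbp3) to 131-fold (Gbp6). Their median log2 ratio was 5.31, above all 10000 random lists (percentile 100). Ifi47 was 16.3-fold higher, while Gbp2b was at the floor on both arrays. Type I interferon-stimulated genes, many of them antiviral effectors, were at least 2-fold higher in 33 of 40 members and 2-fold lower in none, with a median log2 ratio of 2.09 (percentile 100). Parp14 was 22.8-fold, Ifit1 14.9-fold and Mx1 10.4-fold higher. Values within 2-fold included Adar (log2 ratio 0.07), Ifitm3 (0.28) and Ifi203 (-0.45). The gene Ifnb1 for interferon beta was at 17.2 and 21.2, close to the floor.

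In the list of IFNg receptor, JAK-STAT and IRF signalling genes, 11 of 23 members were at least 2-fold higher, none was 2-fold lower, and the median log2 ratio was 0.89 (percentile 100). The transcription factors Irf8, Batf2 (at least 19.6-fold) and Irf1 (10.6-fold), and Nmi (8.48-fold), had the highest values. The feedback inhibitor Socs1 was 5.79-fold and the kinases Jak2 and Jak1 were 5.31-fold and 2.81-fold higher. Further Jak1 probe sets had log2 ratios of 1.05 and, for a dim one, -0.06. The receptor genes lay within 2-fold, with log2 ratios of 0.18 for Ifngr1 and -0.93 for Ifngr2. Socs3 (-0.23) and Irf9 (-0.20) also lay within 2-fold.

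MHC class I antigen presentation and immunoproteasome genes were at least 2-fold higher in 13 of 19 members, with a median log2 ratio of 1.48 (percentile 100). The immunoproteasome subunits Psmb9 (36.6-fold), Psmb8 (15.7-fold) and Psmb10 (6.46-fold), the peptidase Erap1 (10.3-fold) and the peptide transporters Tap1 (8.95-fold) and Tap2 (6.78-fold) led by their chosen probe sets. They had higher folds than the class I chains B2m, H2-K1 and H2-D1. H2-L, H2-T23, H2-T10, H2-T22, H2-Q4 and H2-Q7 matched no probe set naming them alone and are not covered. B2m was 2.45-fold higher and H2-K1 2.07-fold. H2-D1 had a log2 ratio of 0.88, with other probe sets from -0.48 to 2.07, and another probe set of H2-K1 reached 2.56. Class I genes are near-identical paralogs, so which gene such a probe set measures is uncertain. The chaperone Calr (-0.34) lay within 2-fold.

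MHC class II presentation genes were at least 2-fold higher with IFNg in 7 of 13 members and 2-fold lower in none. The chains H2-Aa (at least 76.0-fold), H2-Eb1 (at least 37.1-fold) and H2-Ab1 (18.9-fold), the invariant chain Cd74 (68.3-fold) and the peptide-loading chain H2-DMa (9.59-fold) led the list. The transactivator Ciita was at least 2.36-fold higher, with signals of 2.5 and 48.2, and its other 2 probe sets were at the floor on both arrays. H2-DMb2 was at least 2.76-fold higher by its chosen probe set, but its other probe sets had log2 ratios of -0.43 and -0.16. The lysosomal proteases Ctss (log2 ratio 0.01), Ctsl (-0.06) and Ctsb (-0.16), the reductase Ifi30 (-0.28) and Lgmn (-0.40) lay within 2-fold. The median log2 ratio was 1.24 (percentile 100), and without the probe sets whose IDs mark shared or cross-hybridising sequence it was 0.12 (percentile 87.3, 12 members). No probe set was then left for H2-Aa, and H2-DMb2 took the one at -0.43.

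Myeloid markers were measured beside these genes. Of 18 macrophage, microglia and dendritic cell markers, the oxidase subunit Cybb was 2.33-fold higher, although another probe set of it was lower (log2 ratio -0.78), and 3 were lower: Csf1r (2.62-fold), Fcer1g (at least 2.25-fold) and Laptm5 (at least 2-fold). Ptprc, the pan-leukocyte gene for CD45, had signals of 20.8 and 7. The list's median log2 ratio was -0.20 (percentile 24.5). Only 5 of 17 T, B and NK cell markers were above the floor on either array, none past 2-fold, with a median of -0.22 (percentile 28.1).

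Chemokine and cytokine genes were at least 2-fold higher in 15 of 36 measured members, with a median log2 ratio of 0.54 (percentile 100). The CXCR3 ligands Cxcl9 (285-fold), Cxcl10 (37.8-fold) and Cxcl11 (at least 20.0-fold) and the T-cell attractant Ccl5 (19.6-fold) were highest. Il18bp, which neutralises IL-18, was at least 17.9-fold higher, and the monocyte attractants Ccl8 (11.04-fold), Ccl7 (3.91-fold) and Ccl2 (3.85-fold) were also higher. Ccl9 was 2.61-fold lower. The neutrophil attractants Cxcl1 (-0.33) and Cxcl5 (-0.37) had log2 ratios within 2-fold, while a further one, Cxcl2 (1.00), just passed 2-fold higher. Of 17 complement genes, C2 (4.46-fold) and C1s1 (3.38-fold) passed 2-fold, and the C1 inhibitor Serping1 was 1.98-fold higher. The complement median was 0.30 at percentile 99.97, and at 97.46 with a floor at the pooled 25th percentile.

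Immunosuppressive factors attributed to ocular pigment epithelium lay mostly within 2-fold, in 24 of 28 measured genes. Ptgs2, which catalyses prostaglandin synthesis, was 4.89-fold higher, the nitric oxide synthase Nos2 at least 2.65-fold and the TGF-beta receptor Tgfbr1 2.18-fold. Pomc, the precursor of the melanocortins, was at least 2.01-fold lower. Tgfb1 (log2 ratio -0.33), Tgfb2 (-0.07) and Thbs1 (-0.52), which activates latent TGF-beta, had values within 2-fold. The list's median log2 ratio was -0.08 (percentile 73.7).

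Of 22 measured RPE marker and visual cycle genes, 5 were at least 2-fold lower with IFNg and none was 2-fold higher. The thyroxine and retinol carrier Ttr was 3.04-fold lower, the retinol dehydrogenase Rdh5 2.31-fold, the anion exchanger Slc4a2 2.28-fold, the retinal-binding Rlbp1 2.09-fold and the channel Trpm3 at least 2.03-fold. Otx2, a transcription factor of RPE, had signals of 411 and 388. The visual cycle isomerase gene Rpe65 was at the floor on both arrays (5 and 1.1), as were Best1 and Rgr. The median log2 ratio was -0.15, at percentile 52.0. Of 16 melanogenesis genes, Slc45a2 (at least 3.30-fold) and Tyrp1 (2.45-fold) were lower, Myo5a (2.94-fold) and Atp7a (2.27-fold) were higher, and tyrosinase, Tyr, had a log2 ratio of -0.70. Their median was -0.29, at percentile 4.42.

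Epithelial junction genes had a median log2 ratio of -0.05 (percentile 62.8) over 18 members, with the keratin gene Krt19 2.73-fold higher and the cadherin gene Cdh3 2.59-fold lower. Among 34 fibroblast and mesenchymal genes, the transcription factors Snai2 (2.26-fold) and Zeb1 (2.15-fold) were higher and the smooth-muscle gene Cnn1 was 3.52-fold lower. Another Zeb1 probe set had a log2 ratio of -0.16. Fibroblast genes were far above the floor on both arrays, with signals of 11026 and 9775 for Col1a1 and 13960 and 11076 for Acta2, and their median log2 ratio was -0.17 (percentile 55.4). Markers of other cell types gave medians of -0.39 for endothelial cells and pericytes (14 genes, percentile 11.5, Cspg4 2.35-fold lower), -0.47 for photoreceptors and neural retina (12 genes, percentile 4.20), -0.23 for lens and ciliary or corneal epithelium (8 genes, percentile 27.7) and -0.18 for Schwann cells and the melanocyte lineage (7 genes, percentile 18.2). In the photoreceptor list the neuronal tubulin Tubb3 was at least 7.63-fold higher, and Rom1 (2.95-fold) and Rlbp1 were lower.

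Proliferation genes were lower with IFNg as a list, with a median log2 ratio of -0.51 at percentile 0.01, although only 3 of 29 were at least 2-fold lower. These were the DNA replication genes Mcm2 (3.08-fold) and Tk1 (2.24-fold) and the mitotic kinase Aurkb (2.04-fold). Bub1 (at least 2.49-fold) and Top2a (2.20-fold) were higher, and Mki67 had a log2 ratio of 0.26. The list also holds the cell-cycle inhibitors Cdkn1a (-0.62), Cdkn1b (-0.28) and Cdkn2a (-0.27), whose lower values count toward its median. Apoptosis and inflammatory caspase genes were at least 2-fold higher in 9 of 23 members and lower in none, with a median of 0.50 (percentile 99.9). The necroptosis effector Mlkl was 11.4-fold, the inflammatory caspase Casp4 11.3-fold, the death receptor Fas 6.93-fold and the inflammasome adaptor Pycard 6.26-fold higher.

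Metabolic and stress lists had medians of 0.34 or less. In the tryptophan, arginine, nitric oxide and redox list, Acod1, the tryptophanyl-tRNA synthetase Wars (8.67-fold), Nos2 and Cybb were the 4 of 12 members at least 2-fold higher, and Ido1, which degrades tryptophan, was at 8.1 and 29.4. Its median log2 ratio was 0.34 at percentile 99.1, and 0.15 at percentile 87.0 with a floor at the pooled 25th percentile. Stard4 (3.06-fold), Idi1 (2.93-fold) and Hmgcs1 (2.17-fold) were higher among 16 cholesterol synthesis genes, whose median was 0.29 (percentile 97.9, and 96.6 with a floor at the pooled 75th percentile). The chaperones Hspa1a (2.92-fold), Hspa5 (2.40-fold), Hsp90aa1 (2.30-fold) and Hspa1b (2.25-fold) and the transcription factor Atf3 (2.09-fold) were the 5 of 25 immediate-early and stress genes past 2-fold, and that list's median was 0.09 (percentile 97.4). None of 16 housekeeping genes passed 2-fold, with a median of -0.10 (percentile 73.5). Actb had a log2 ratio of -0.03 and Gusb, the furthest from 0, of -0.82.

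**Figure D3:**
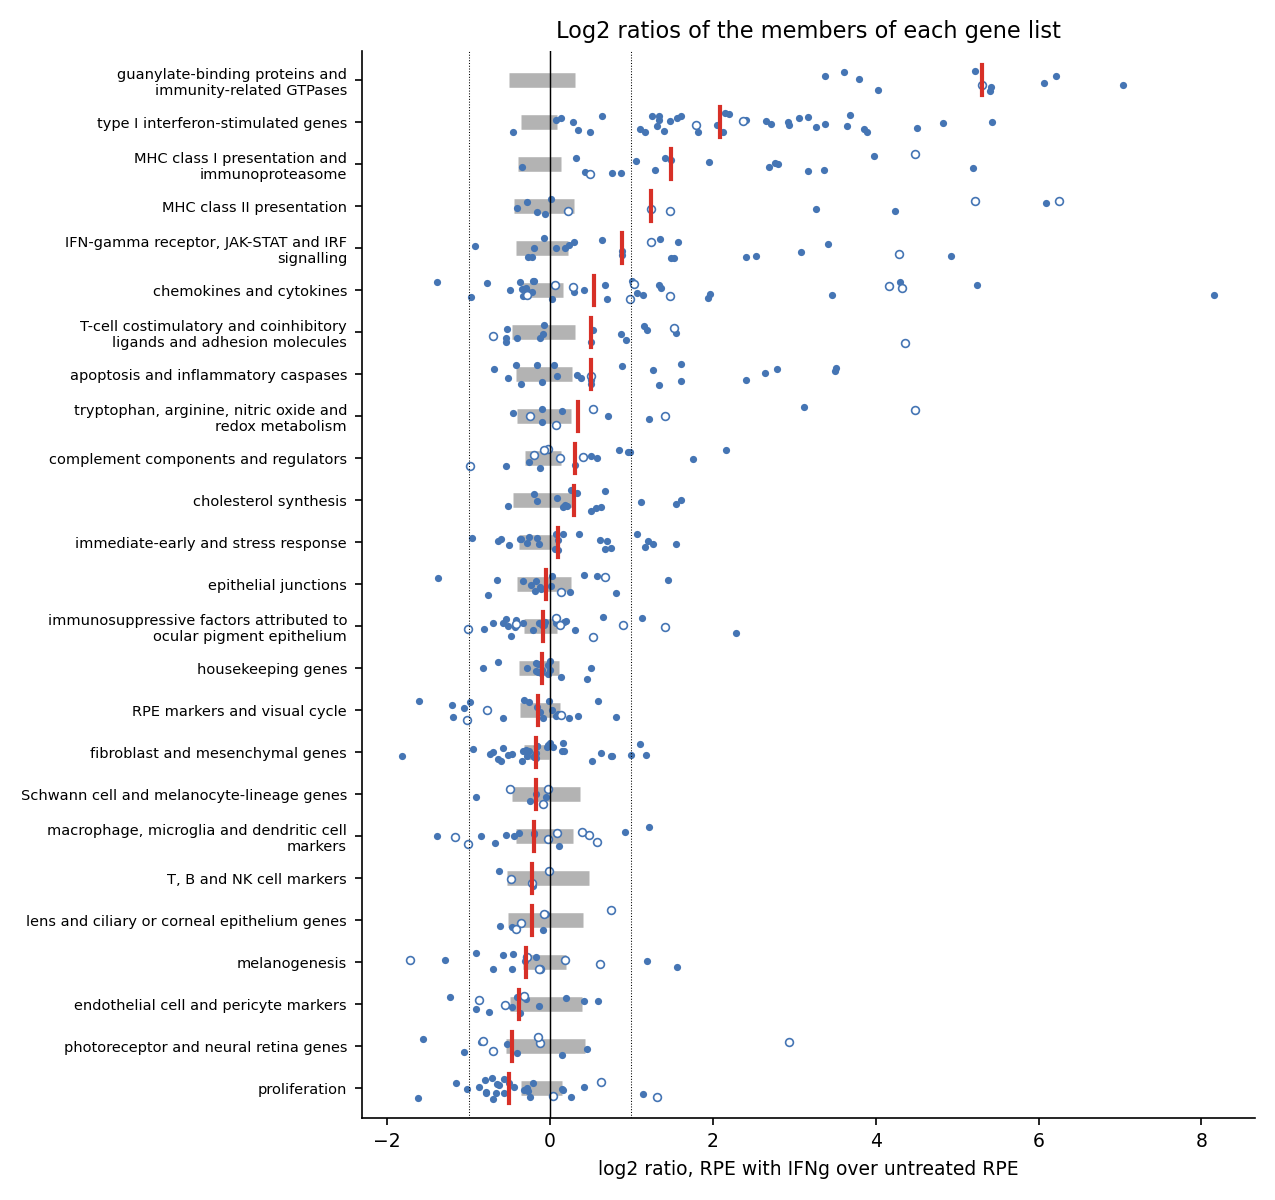
Log2 ratio of RPE with IFNg over untreated RPE for each measured member of 25 gene lists (filled, both arrays above the floor; open, 1 array at the floor), with each list's median as a red bar and the central 95% of medians of matched random lists in grey. Medians run from -0.51 for proliferation to 5.31 for guanylate-binding proteins and immunity-related GTPases.

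RNA quality controls on the arrays were close but not equal. The 3-prime to 5-prime signal ratio of the Actb control probe sets was 1.24 untreated and 1.38 with IFNg, that of Gapdh was 0.908 and 1.03, and that of the dimmer Pcx was 2.27 and 1.55. The bright spike-in probe sets bioC, bioD and cre had ratios of IFNg to untreated signal from 0.986 to 1.15. The bioB spike-in probe sets were under the floor on both arrays, at 1.1 to 5.5 untreated and 2.6 to 18.1 with IFNg, so they show nothing about dim signals.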

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

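The comparisons of probe sets outside the gene table were chosen after the gene results had been seen. Probe sets that the annotation ties to no gene carried signal that the gene counts leave out. Of 9160 such probe sets, 2950 were above the floor on 1 or both arrays, 353 were at least 2-fold higher with IFNg and 73 at least 2-fold lower (82.9% higher, Wilson 95% interval 79.0 to 86.1, over probe sets that are not independent). At 8-fold, 6 were higher and 0 lower. Among probe sets tied to 1 gene the share was 66.6%. Probe sets tied to several genes gave 58 that were at least 2-fold higher and 26 at least 2-fold lower.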

How the results depend on the processing

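None of the alternatives was added after the results were seen. No paired analysis was possible because each group holds 1 array. Of 1480 values of 168 single genes under the alternatives, 1362 lay within 1.5-fold of the reported value, 115 lay further off with the same sign and 3 reversed, while 88 dropped under 2-fold. The 3 were all H2-DMb2, with log2 ratios of -0.43 with a floor at the 25th percentile, -0.43 without shared-sequence probe sets and -0.28 with a pseudocount of 16, each time with another of its probe sets chosen. Leaving out the rescaling can hardly move a single gene. Averaging probe sets or leaving out shared-sequence ones cannot move a gene whose only probe set is not of that kind. Part of the agreement of single genes was therefore fixed in advance.

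The counts of genes 2-fold higher and lower were 2258 and 2059 with a floor at the 25th percentile, 574 and 163 with one at the 75th, and 591 and 357 with probe sets averaged, 2287 and 2378 at 1.5-fold, and 336 and 59 at 3-fold. Other scalings gave 971 and 751 (a common 75th percentile), 1013 and 716 (quantile) and 1162 and 618 (loess). The bound for Cd274 was 4.84-fold with a floor at the 75th percentile, as a higher floor lowers every bound.

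Of 246 list medians, 243 lay within 1.5-fold of the reported value. Leaving out the matching cannot move a median and leaving out the rescaling hardly can, so the agreement of those medians was fixed in advance. Among lists in the outer 5% of random lists as reported, 0 reversed, and sign changes of other lists were not counted. The 3 medians further off were all of class II presentation, at 0.55 with a pseudocount of 16, 0.29 with probe sets averaged and 0.12 (percentile 87.3) without shared-sequence probe sets. In the last case H2-Aa has no probe set left and H2-DMb2 takes another one (log2 ratio -0.43). Complement (97.46 and 97.47), cholesterol synthesis (96.6 and 97.1) and tryptophan metabolism (87.0 and 96.5) left the outer 5% of random lists under another floor and without matching, and the last also with probe sets averaged (94.9). Stress genes entered it under 6 alternatives (97.6 to 99.6), melanogenesis under quantile and loess scaling (2.20 and 1.98) and photoreceptor genes under loess (2.44). The cause was not tested where none is given. Signal over background limits dim genes.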

Other observations

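The gene families described first, and the tests of scaling, dim probe sets and probe-set-specific signal for the excess of higher genes and of leukocytes and faulty probe sets for class II genes, were chosen after the results had been seen. Poly(ADP-ribose) polymerase genes were higher with IFNg as a family, at least 2-fold in 7 of 11, with a median log2 ratio of 1.55 (percentile 100 among matched random lists). Parp14, Parp9 (8.30-fold) and Parp12 (3.05-fold) belong to the interferon-stimulated list, and Parp11 (4.38-fold), Tiparp (3.17-fold), Parp8 (2.92-fold) and Parp3 (2.34-fold) do not. Tripartite motif genes, many of them ubiquitin ligases, were 2-fold higher in 9 of 38 and lower in none (median 0.25, percentile 98.99), led by Trim30a (14.5-fold) and Trim12a (9.51-fold). Of the 9, Trim30a and Trim21 (6.56-fold) belong to the interferon-stimulated list. Of 4 schlafen genes, Slfn8 (12.8-fold), Slfn9 (at least 4.80-fold) and Slfn2 (3.23-fold) were higher.

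Other families, taken by the start of the gene symbol, also differed. Genes with a Usp symbol, most of them ubiquitin-specific proteases, had a median of 0.42 (percentile 99.95), with 11 of 44 at least 2-fold higher, among them Usp15 (3.59-fold) and Usp1 (3.56-fold) and, from the interferon-stimulated list, Usp18 (2.78-fold), and 2 lower. The 11 include Usp6nl, which is there by its symbol alone. Genes with a Zfp symbol, most of them zinc finger genes, had 33 of 266 higher and 12 lower (median 0.13, percentile 100). Translation initiation factors had 11 of 42 higher, such as Eif4e3 (4.08-fold) and Eif3a (2.69-fold), and none lower, with a median of 0.06 (percentile 98.7). Scaling to a common 75th percentile, which shifts the ratios of all genes above the floor alike, gave a median of -0.02 at percentile 98.4. Solute carriers had a median of -0.27 (percentile 0.01), with 18 of 234 lower, among them Slc26a11 (3.40-fold) and Slc7a8 (2.43-fold), and 9 higher. Collagens had 3 of 30 lower and none higher (median -0.39, percentile 1.04), namely Col23a1 (2.31-fold), Col8a2 (2.27-fold) and Col6a2 (2.04-fold). Apart from the initiation factors, the medians of these families kept their sign under the other 3 scalings. The initiation factors kept their place among random lists, at percentiles from 98.4 to 99.31 under all scalings. Base composition and transcript length were not tested, as no probe or transcript sequence was used here.

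NADH dehydrogenase subunits had a median of -0.28 (43 genes, percentile 12.3) with none past 2-fold, and mitochondrial ribosomal proteins -0.26 (76 genes, percentile 12.4), with Mrpl1 (2.28-fold), Mrps18c (2.10-fold) and Mrpl47 (2.09-fold) higher and Mrpl57 (2.20-fold) lower. Cytosolic ribosomal proteins had -0.08 (44 genes, percentile 91.6), and 0.05 (percentile 93.2) under loess scaling, with Rpl39 the exception past 2-fold.

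More genes were at least 2-fold higher than lower with IFNg, 66.3% of those past 2-fold, while the median log2 ratio of all measured genes was -0.12. Scaling and the noise of dim probe sets are argued against as the whole cause: the lowest share under 3 other scalings was 56.4% (Wilson interval 54.0 to 58.7), and the share was 75.8% in the brighter 5 of 10 brightness bins against 59.2% in the dimmer 5. Genes are not independent, so the intervals in this paragraph describe these 2 arrays and not other cultures. Among genes in no list, 64.4% of 1549 were higher. Signal specific to some probe sets could be examined only for the 913 of 1695 genes past 2-fold that had another measured probe set. For these it is argued against as the whole cause, since of 283 whose other probe sets also averaged past 2-fold the same way, 84.1% were higher (interval 79.4 to 87.9). Of the 630 without such support 74.0% were higher as well, so a part of it stays open. Both shares exceed 66.3%, so the share was below 66.3% among genes with no other measured probe set, which the comparison cannot cover. A broad response to IFNg may add to the excess, but at 1.5-fold the numbers were 2287 higher and 2378 lower. The excess was thus seen at 2-fold and not at 1.5-fold. Since the median was below 0 and no setting centred it, the size at which the excess begins cannot be told. Large decreases of dim genes are also capped by the floor.

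MHC class II genes were higher with IFNg in cultures where myeloid cells could be a candidate source. Measured markers of the macrophage, microglia and dendritic cell list with an untreated signal under 100, and in no other list, had a median log2 ratio of 0.030 (12 genes, quartiles -0.36 and 0.42, highest Cd53 at 0.92). Brighter markers, such as Csf1r, were left out of these 12, and the median of all 18 measured markers of that list was -0.20. More leukocytes cannot be told apart from the pattern, since only 5 of the 12 reached 40.8, the floor times 2, on an array (median -0.84). A single faulty probe set per gene cannot be told apart from the pattern for all 7 higher genes, since only 6 probe sets beside the chosen ones were above the floor, of which 66.7% were at least 2-fold higher (Wilson interval 30.0 to 90.3, over probe sets that are not independent), and 4 more were at the floor on both arrays. The higher ones all belong to H2-Aa and H2-Ab1, and H2-Eb1 and Cd74 have 1 probe set each. A response of the cultured cells to IFNg or another difference between the cultures stays open, as does activation of myeloid cells already present, since Mpeg1, a macrophage gene in no list, was at least 43.5-fold higher, and none of these was tested.

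Proliferation genes had a lower median with IFNg. Noise of dim probe sets is argued against by the 23 members above the pooled 75th percentile on both arrays. Their median was -0.57, under the random range of -0.39 to 0.18. Of these 23 members, 18 were below 0, among them the inhibitors Cdkn1a and Cdkn1b. That count was not set against random lists, and bright genes in general lay below 0 (median -0.21 in the brightest of 10 bins). The choice of 1 probe set per gene is argued against by a median of -0.37 with probe sets averaged, under the random 2.5th percentile of -0.33. Slower growth with IFNg may be the reason, but Top2a, Bub1 and Mki67 were not lower and the inhibitor Cdkn1a had -0.62. Cell density and the length of serum-free culture were not tested and stay open.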
